A study of Tachysurus fulvidraco x Tachysurus vachelli with 6 samples.

How the data were processed

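Small RNA libraries from the intestine of hybrid yellow catfish (a cross of Tachysurus fulvidraco and Tachysurus vachelli) were compared between 3 untreated control samples and 3 samples taken after 16 h of transport. Total RNA was extracted with Trizol, libraries were made with a TruSeq small RNA kit and sequenced on an Illumina HiSeq, per the labels' protocols. Reads were cleaned with the ACGT101-miR program, which removed adapter dimers, junk, low-complexity reads, common non-coding RNA families and repeats, per the labels' protocols. Other transport times and the recovery period named in the series design were not analysed here.

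The deposited table lists 1337 rows of mature miRNA sequences. Per the file headers, reads were matched to known precursors of selected species and to a genome, and each row carries 1 of 5 mapping classes, among them features matched only to known mature miRNAs with no genome position, and candidate miRNAs (names beginning with PC) called from hairpin folding alone. The genome build, the aligner and the database release were not given in the sources used here, so scaffold positions are given as the file lists them, with no gene annotation. A further 53 emptied lines were left out. The authors deposited raw values that behave as estimated counts: they are mostly whole numbers, and 221 of the 252 sequences listed in several rows have fractions. Of these 221, 91.0% became whole (within 1e-06) after multiplication by the number of rows, as reads divided equally between the rows of a sequence would, and 20 did not. Fractions also stood in 124 of the 806 sequences listed in 1 row, which such a division does not give; their origin was not given in the sources used here. The authors also deposited a normalized signal, which equals the raw value times 1 factor per library. These factors, computed here as the ratio of the totals, ran from 0.789 to 2.18 and their method was not given in the sources used here. The columns named for the stressed group were taken as the transport samples, since the labels name no other treated group.

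Rows with the same mature sequence and the same values were kept once, which gave 1058 features, 781 with a known miRNA name and 277 candidates. Where reads were divided between rows, such a sequence carries the share of 1 row, and summing the rows was tried as an alternative. Values were rounded to whole counts. Totals over features were 3620502, 5550507 and 5524373 counts in controls 1 to 3 and 6655227, 6626476 and 7196944 counts in transport samples 1 to 3. Totals over all rows were larger, from 4.74e+06 in control 1 to 9.76e+06 in transport 3. Percents of counts are of the totals over features. For a sequence listed in 1 row they are therefore higher than its percent of all rows, which was not computed. Copies of a miRNA that differ by end or by a base are separate features in the file, and reads shared between near-identical family members remain uncertain. Suffixes such as R+1 or 1ss20TA record how a sequence differs from the database entry.

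Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood fit, group as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled and are given as mean ± SD over 3 libraries. Fold changes are log2, transport minus control, with the standard error of the fit. Counts summed over features with the same bases 2 to 8 (the seed) were tested in the same way. A total of 19 miRNA lists (tissue markers, stress, immune and family lists) were fixed before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and camera with an estimated correlation and fry were run beside it. The log2 ratio of the 5p to the 3p arm of a precursor, with 0.5 added to each count, was tested with limma 3.58.1 for pairs with a mean of at least 10 counts in each arm. Shares of counts were compared with exact two-sided permutation tests, which cannot give a p below 0.1 with 3 libraries against 3. Wilson intervals at 95% and the floor of 3 counts for a value of 0 cover counting error only, since reads without molecular identifiers are not independent molecules.

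The rule for named miRNAs was fixed before the data were examined: features past the threshold with a mean of at least 10 CPM and no overlap between groups (up to 10 in each direction), otherwise the 10 features with the smallest p as values, then the 5 most abundant features, and for each list its most abundant member and the member with the smallest p. This gave 41 features. Nothing in the labels says how many fish stand behind a sample or that samples with the same number are related, so p-values measure the spread between these samples. Library pairs were compared by chi-square, and no pair agreed within sampling noise.

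The tests were tried on counts simulated with the means and library sizes of these libraries, at their dispersions except where another is given, with 200 changed features for edgeR. For transport against control, edgeR recovered 8.42% of features changed by 1 on the log2 scale and 51.1% of those changed by 2, out of 520 features, with 0 false calls. With the dispersions divided by 4, recovery over 541 features was 48.0% and 91.4%, with 1 false call. The camera test called a let-7 list moved by 1 among 567 features. Features were drawn independently of each other there, so this run does not cover lists whose members vary together. The arm test recovered 65.0% of pairs moved by 2 among 70 pairs whose ratios were drawn with each pair's own residual SD, with 2 false calls. With the 2 arms varying independently, which these libraries' ratios need not do, it recovered 0 of 39 moved pairs among 75 at the observed dispersions, with 0 false calls, and 90.0% among 73 pairs at a dispersion of 0.1 for every feature, with 1 false call.

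Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, upper-quartile scaling, library totals alone, no filter, a mean of at least 10 CPM, the DESeq2 Wald test, limma-voom, limma on the authors' normalized values with pseudocounts of 1 and 0.1, the sample number as a block, each library left out in turn, known names alone, removal of the 10 most abundant features, and every row kept. Added after the data were seen were summed rows, features with a genome position alone, library quality weights, removal of both forms of miR-143-3p or of PC-3p-1_6188007, and 2 settings that combine a change with the removal of control 1. Figures were drawn with matplotlib 3.10.9.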

Results

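MicroRNAs were profiled in the intestine of hybrid yellow catfish from 3 untreated control samples and 3 samples taken after 16 h of transport. The totals ran from 3620502 counts in control 1 to 7196944 counts in transport sample 3, and between 667 and 786 features were detected per library. The most abundant features were PC-3p-1_6188007 (a candidate feature whose sequence is that of miR-143-3p with 1 further base), miR-194a, miR-143_1ss20TA, miR-22b and miR-21. In this ranking a sequence listed in several rows, such as let-7a with 7, counts with the values of 1 row. The epithelial miR-194a averaged 109201 ± 11445 CPM in controls and 121812 ± 7583 CPM after transport (n = 3 each). For miR-22b the averages were 49594 ± 11987 and 56411 ± 9693 CPM, and for miR-21, a miRNA of inflammation and repair, 42333 ± 12328 and 40248 ± 1983 CPM. Control 1 stood apart from the other libraries. On log2 CPM of the 567 tested features its correlation across features with the other 5 libraries averaged 0.862, against averages of 0.933 to 0.947 for the others, and the first principal component, with 62.2% of the variance, placed it alone at one end.

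**Figure D1:**
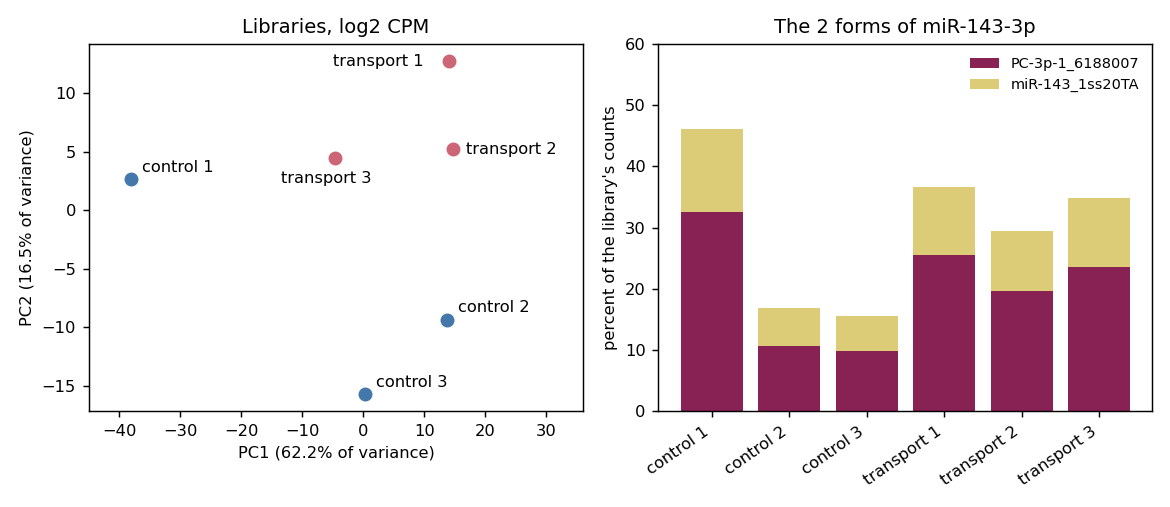
Left, principal components of the log2 CPM of the 567 tested features, with 1 point per library (blue, control; red, transport 16 h) and the percent of variance on each axis. Right, percent of each library's counts over features held by the 2 forms of miR-143-3p (stacked bars). In that total a sequence listed in several rows counts with the values of 1 row. Control 1 holds 46.1% and the transport libraries 29.5% to 36.5%, against 16.8% and 15.5% in controls 2 and 3.

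The comparison of transport with control asks which intestinal miRNAs differ after 16 h of transport stress. The features with the smallest p-values included 4 that were more abundant in all 3 transport libraries than in any control. The muscle miRNA miR-499, encoded within a myosin gene in vertebrates, averaged 182.9 ± 45.4 CPM after transport and 78.5 ± 12.3 CPM in controls, a log2 fold change of 1.22 ± 0.28 (SE, n = 3 each). A feature named as a form of miR-10a-5p, a miRNA of the Hox gene clusters, averaged 1236 ± 73.5 against 543 ± 171 CPM (gmo-miR-10a-5p_1ss1TC, log2 fold change 1.19 ± 0.28). Its listed sequence differs from that of miR-10b-5p only at base 1. The log2 fold change was 0.02 ± 0.29 for the more abundant miR-10b-5p and -0.28 ± 0.26 for the feature named miR-10a. It was 1.16 ± 0.39 for miR-10a-5p_R+1_1ss1TC, whose name records the same base change. The matrix-regulating miR-29b averaged 105.3 ± 3.61 against 50.8 ± 11.5 CPM, a log2 fold change of 1.05 ± 0.25. The gut miRNA miR-192-5p, in a form without a genome position, averaged 61.8 ± 7.50 against 30.7 ± 5.63 CPM. More abundant in all 3 controls than in any transport library were the liver miRNA miR-122-5p (72.3 ± 48.6 against 11.3 ± 5.25 CPM, log2 fold change -2.68 ± 0.73), miR-2478_L-2 (326 ± 108 against 143.5 ± 17.0 CPM, log2 fold change -1.18 ± 0.31) and the candidate PC-5p-846_3903 (179.4 ± 44.5 against 92.0 ± 17.9 CPM, log2 fold change -0.96 ± 0.27). A pair of short forms of miR-11987 had 52, 36 and 36 counts (L-1 form) and 61, 27 and 16 counts (L-2 form) in controls 1 to 3, and at most 2 counts in any transport library. The rarer miR-2478_L-2_1ss4TA had 7, 13 and 11 counts in the controls and 0 in each transport library, which allows up to 0.453 CPM without TMM scaling. The listed precursors of the 2 miR-11987 forms run only from 32173 to 32199 and from 21960 to 21986. Both miR-2478 forms are 18 nt long and end in CCA. Whether these short sequences are mature miRNAs was not tested.

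None of these differences passed the threshold. Of 567 features tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.592. At an unadjusted p under 0.05 there were 44 features, 22 higher and 22 lower after transport, where 28.4 would be expected by chance. That count was 130 without control 1 (55 higher and 75 lower) and 23 without transport 2. Ranges of the groups did not overlap for 83 features, 14.6% of those tested, against the 10% that chance gives for 3 against 3. DESeq2's Wald test called 21 features, 13 of them with counts in control 1 alone. Among its other 8 were miR-499, miR-29b, gmo-miR-10a-5p_1ss1TC, miR-122-5p, miR-2478_L-2 and both forms of miR-11987. The last of the 8 was miR-127-5p, with 96 counts in control 1, 17 in control 3 and 0 in every other library. miR-127 belongs to the placental mammal cluster described below.

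The count depended on control 1. Without it, edgeR called 4 of 611 features, each with an adjusted p of 0.0369. Both forms of miR-143-3p, the miRNA of smooth muscle, were higher after transport: PC-3p-1_6188007 averaged 257243 ± 43969 CPM (n = 3) against 86847 ± 7978 CPM (n = 2), a log2 fold change of 1.57 ± 0.20, and miR-143_1ss20TA averaged 119813 ± 13278 against 50423 ± 5306 CPM, a log2 fold change of 1.25 ± 0.18. The others were lower, miR-122-5p by a log2 fold change of -3.14 ± 0.42 and miR-2478_L-2 by -1.44 ± 0.21. With all 6 libraries the log2 fold changes of PC-3p-1_6188007 and miR-143_1ss20TA were 0.29 ± 0.70 and 0.30 ± 0.57, and both forms were more abundant in control 1 (433599 and 181621 CPM) than in any transport library. Both lie on scaffold NW_020848201.1, minus strand, with precursors at 12569636 to 12569722 and 12569684 to 12569756, beside the precursor of miR-145-5p at 12569354 to 12569421. PC-3p-1_6188007 (TGAGATGAAGCACTGTAGCACT) shares all 21 bases of miR-143_1ss20TA (TGAGATGAAGCACTGTAGCAC) and differs from its listed hairpin by G22T, counted from 1 at the 5′ end of the mature sequence.

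**Figure D2:**
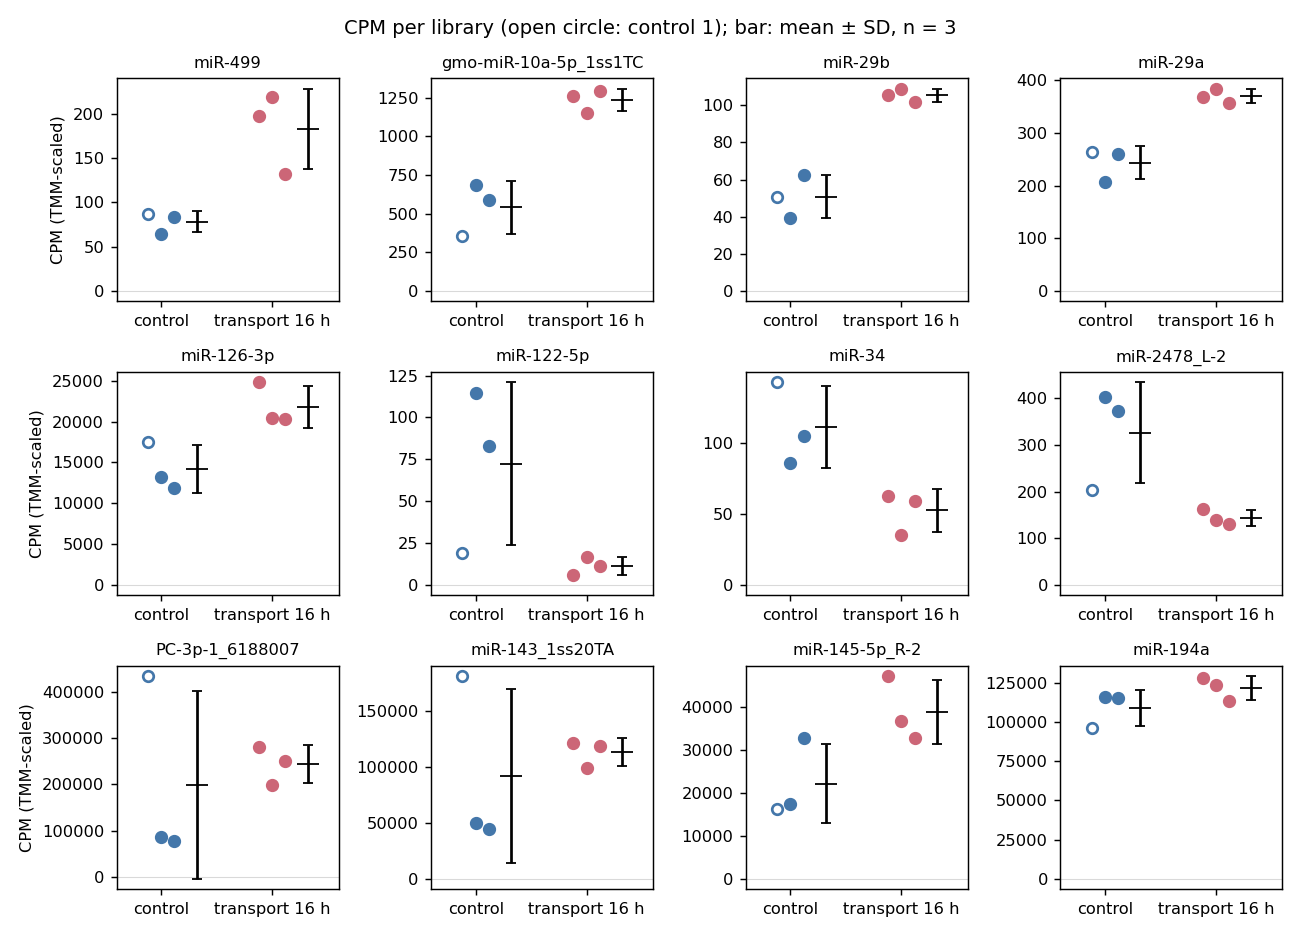
TMM-scaled CPM of 12 miRNAs in each library (points, with control 1 as an open circle) and the mean ± SD of each group (bars, n = 3), on linear axes that include 0. For miR-499, gmo-miR-10a-5p_1ss1TC and miR-29b the groups do not overlap, and for both forms of miR-143-3p control 1 lies above the 3 transport libraries; the edgeR test called 0 features.

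Scaling by library totals alone moved the median of all tested features by -0.22 on the log2 scale. Among the miRNA lists, the miR-29 family, known for targeting collagen and other matrix transcripts, was higher after transport relative to the other tested miRNAs by camera (adjusted p = 0.0397), a call that was lost with an estimated correlation (adjusted p = 0.353) and was not made by fry (adjusted p = 0.127). Of its 8 tested members, 7 had a positive fold change and the median was 0.56 (0.43 to 0.64 under the other scalings). miR-29a averaged 370 ± 13.4 against 244 ± 31.4 CPM, a log2 fold change of 0.60 ± 0.20, and 0 members passed over all features, with 1 (miR-29b, adjusted p = 0.0395) adjusted over the list alone by edgeR, a call kept without control 1 or control 3 and lost without any of the other 4 libraries. The precursors of miR-29b (TAGCACCATTTGAAATCAGTGT) and miR-29a (TAGCACCATTTGAAATCGGTTA) are each listed in 2 rows, one of them on scaffold NW_020848400.1, minus strand, at 3891046 to 3891126 and 3890849 to 3890909. The exception was miR-29a_L+1R-1_1ss10TC, at 343 CPM in control 1 and 1.61 CPM in control 2. The list was the only 1 of 16 past the threshold in camera. The call was lost without control 2, control 3, transport 1 or transport 3, with camera adjusted p of 0.512, 0.0518, 0.0899 and 0.134.

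Markers of vessels, smooth muscle and nerves in the gut wall did not pass the threshold with all 6 libraries in the main fit. With no filter on low counts all 3 lists passed camera (adjusted p = 0.0162 endothelial, 0.0188 smooth muscle and 0.0025 neural), and none did with an estimated correlation (adjusted p = 0.354, 0.409 and 0.354). With the sample number as a block the endothelial and neural lists passed (adjusted p = 0.0389 for both, and adjusted p = 0.717 for both with an estimated correlation). All 4 endothelial members (miR-126) had a positive fold change, with a median of 0.52 (0.29 to 0.59 under the other scalings) and an adjusted p of 0.0572 by camera. The abundant miR-126-3p averaged 21837 ± 2566 CPM after transport and 14193 ± 2978 CPM in controls, a log2 fold change of 0.62 ± 0.23, and the rarer miR-126b-3p 34.9 ± 11.8 against 13.7 ± 5.73 CPM. The smooth muscle list had 4 of 5 members above 0 and an adjusted p of 0.105, with miR-145-5p at 38864 ± 7465 against 22099 ± 9213 CPM. Without control 1, both lists passed camera (adjusted p = 0.0491 and adjusted p = 0.0260), and with an estimated correlation neither did (adjusted p = 0.682 for both). Without transport 2 these lists and the neural list passed, each with an adjusted p of 0.0395 (adjusted p = 0.618 for each with an estimated correlation). In control 1 the median of the smooth muscle list differed from controls 2 and 3 by 0.62 ± 0.45 on the log2 scale (SE over members), that of the endothelial list by 0.57 ± 0.48 and that of the erythroid list by 1.75 ± 0.53. The neural list differed by -0.42 ± 0.30, the leukocyte list by -0.39 ± 0.39, the striated muscle list by -0.29 ± 0.38, the epithelial list by -0.28 ± 0.18 and the pancreas list by -0.21 ± 0.48. Of 26 neural members 19 had a positive fold change, with an adjusted p of 0.0557 by camera and a median of 0.24 that turned to -0.02 with library totals as the only scaling and was 0.03 without control 1 (adjusted p = 0.368), the lowest of 0.03 to 0.36 with each library left out. The neural miR-137b averaged 260 ± 62.0 against 148.8 ± 43.2 CPM and miR-128-3p 2824 ± 260 against 3059 ± 494 CPM. The estimated correlation of the neural list was 0.0094, near the preset 0.01, yet its unadjusted camera p rose from 0.0070 to 0.053. For the endothelial list it was -0.034, and that p rose from 0.0107 to 0.060. A call lost with an estimated correlation thus need not reflect members that vary together.

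The 24 epithelial members (miR-192, miR-194, miR-200 and related families) had a median of -0.32 (-0.52 to -0.29 under the other scalings, and -0.39 to -0.11 with each library left out), with 17 below 0 and a camera adjusted p of 0.173. Among features with a genome position alone the list passed as lower (18 members, adjusted p = 0.0207, and adjusted p = 0.608 with an estimated correlation), a setting chosen after the data were seen. The striated muscle list of 12 was split evenly, 6 above and 6 below 0, with miR-1 at 8103 ± 1582 against 5889 ± 3238 CPM. Its member miR-499 was the 1 feature past the threshold adjusted over the list alone (edgeR adjusted p = 0.0466), and was so in 2 of the 6 fits that left out a library, those without control 1 or transport 3. The liver list held only miR-122-5p, so that its edgeR p of 0.0094 adjusted over the list alone is the unadjusted p, and it did not pass over all features or adjusted over the lipid and energy list alone, which also holds it (adjusted p = 0.160). Its precursor is listed on scaffold NW_020847786.1, plus strand, at 684980 to 685038. The pancreas list of 13 had a median of -0.16 (camera adjusted p = 0.876), which ran from -0.43 without transport 2 to 0.02 without control 2 (adjusted p = 0.794) with each library left out, with miR-375 at 1488 ± 137.4 against 2256 ± 851 CPM and miR-148-3p at 1873 ± 759 against 2951 ± 2102 CPM. The erythroid list had 4 of 4 features below 0 and did not pass (median -0.56, adjusted p = 0.415), and with each library left out its median ran from -0.91 without control 3 to 0.03 without control 1 (adjusted p = 0.864). In that list miR-451 averaged 638 ± 262 against 911 ± 424 CPM and miR-144-3p 5.08 ± 1.82 against 15.1 ± 18.3 CPM.

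Immune miRNAs, the subject named in the series title, were evenly divided. Of 30 tested members 15 had a positive and 15 a negative fold change, the median was 0.02 (-0.14 to 0.07 under the other scalings and -0.09 to 0.16 with each library left out), and the camera adjusted p was 0.898. The negative members include 2 with the same values, miR-181c-5p_R+1_1 and miR-181c-5p_R+1_2 (log2 fold change -0.37), which are not separate evidence. Among features with a genome position alone, a setting chosen after the data were seen, the median of 25 members was 0.14 (camera adjusted p = 0.629). The members removed there include miR-21-5p_R+1 (log2 fold change -4.30), which had 19990 counts in control 1. By edgeR 0 members passed either over all features or adjusted over the list alone. The lymphocyte miRNA miR-181a-5p averaged 3212 ± 334 CPM after transport and 4576 ± 814 CPM in controls. Within the leukocyte list (5 members, adjusted p = 0.826), miR-142 averaged 1305 ± 349 against 843 ± 265 CPM and miR-155, a miRNA of activated immune cells, 325 ± 79.1 against 487 ± 121.6 CPM. The hypoxia-linked miR-210 averaged 1326 ± 213 against 1494 ± 197 CPM, and the p53-linked miR-34 52.4 ± 15.1 against 110.9 ± 28.97 CPM, a log2 fold change of -1.08 ± 0.33, with an adjusted p of 0.898 for their list of 7.

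Family lists gave the following values. The 31 let-7 features had a median of -0.32 (-0.53 to -0.26 under the other scalings, and -0.37 to -0.17 with each library left out), with 24 below 0 (camera adjusted p = 0.135). They include 2 features with the same values, let-7d-5p_R+2_1 and let-7d-5p_R+2_2, whose log2 fold change of -0.32 is the median. Among features with a genome position alone, a setting chosen after the data were seen, the median of 29 let-7 features was -0.15 (camera adjusted p = 0.210). In that family let-7a, with the values of 1 of its 7 rows, averaged 14668 ± 113.8 against 15429 ± 547 CPM. For let-7i the averages were 156.9 ± 27.3 against 431 ± 374 CPM, with 862 CPM in control 1. The miR-17-92 type list of 25 had a median of 0.26, which was -0.02 with library totals as the only scaling, 0.01 without control 1 and -0.03 to 0.35 with each library left out, and an adjusted p of 0.104. Its most abundant member miR-92a averaged 10205 ± 4536 against 12568 ± 6649 CPM, and miR-106 averaged 713 ± 52.6 against 541 ± 82.5 CPM. The miR-30 family (18 members) had an adjusted p of 0.943, with miR-30b-5p at 12160 ± 2157 against 12897 ± 5244 CPM and miR-30a-3p at 54.0 ± 5.37 against 81.3 ± 9.56 CPM. The lipid and energy list (17 members) had an adjusted p of 0.876, with miR-27b-3p at 5441 ± 1488 against 5321 ± 1834 CPM. Of the miR-183 cluster, miR-183 averaged 4.62 ± 2.02 against 3.20 ± 1.23 CPM, and miR-182 had 12, 20 and 29 counts in the transport libraries and 0, 9 and 0 in the controls. The embryonic miR-430 family, taken as a background check, had 5 features in the table and 0 with enough counts to be tested.

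Camera did not call the Hox-cluster miRNAs (miR-10 and miR-196) as a list (adjusted p = 0.876). Fry's test for change in either direction gave an adjusted p of 0.0087, and this list was the only 1 of 16 to pass it. The fold change was positive in 8 of 11 miR-10 features and negative in 5 of 5 miR-196 features. By edgeR 0 members passed over all features or adjusted over the list alone, and miR-10 was not tested against miR-196. The medians of miR-10 and miR-196 were 0.34 (0.11 to 0.37 under the other scalings) and -1.07 (-1.33 to -1.06). Leaving out each library gave medians of 0.28 to 0.59 and -2.04 to -0.59. The most abundant member, miR-10b-5p, averaged 11873 ± 3645 against 11715 ± 2474 CPM. The fry call was lost without control 2 or control 3 (adjusted p = 0.137 and adjusted p = 0.0511), and without control 1 fry's test passed for 12 lists.

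**Figure D3:**
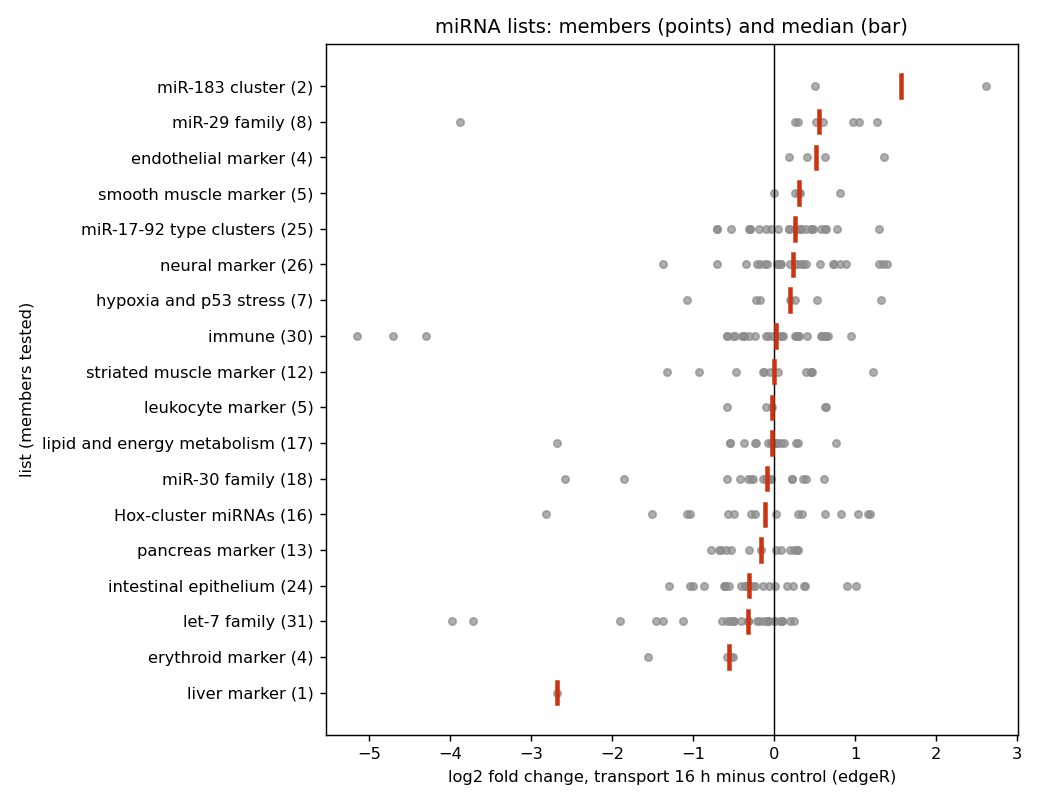
Log2 fold change of every tested member (grey points) of each list, transport minus control, with the list median (red bar) and the number of members tested in brackets. The miR-29 family has 7 of 8 members above 0, with a median of 0.56, and is the only list past camera's threshold (adjusted p = 0.0397, and adjusted p = 0.353 with an estimated correlation).

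Features that share a seed, and so many predicted targets, were also tested together. Of 324 seed families tested by edgeR, 0 passed, 29 had an unadjusted p under 0.05 (16.2 expected by chance) and the smallest adjusted p was 0.532. The miR-499 seed had a log2 fold change of 1.25 ± 0.30 and the seed shared by 6 miR-2478-type features -1.17 ± 0.27. Without control 1, 3 seed families passed, those of miR-143-3p, miR-2478_L-2 and miR-122-5p (log2 fold changes 1.47 ± 0.17, -1.42 ± 0.18 and -3.11 ± 0.45).

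The balance between the 2 arms of a precursor was compared for 70 pairs. None passed in limma, 7 had an unadjusted p under 0.05 and the smallest adjusted p was 0.423. The largest of these differences by p was at miR-15a, where the log2 ratio of the 5p to the 3p arm averaged 7.34 ± 0.22 after transport and 5.78 ± 0.70 in controls. Without control 1, 9 of 63 pairs passed, among them miR-15a (change of 1.96 ± 0.27, limma adjusted p = 0.0024) and miR-192 (2.09 ± 0.34, adjusted p = 0.0031) toward the 5p arm, and miR-193b (-1.40 ± 0.20, adjusted p = 0.0024) and miR-200a (-1.16 ± 0.19, adjusted p = 0.0031) toward the 3p arm. These pairs were chosen after their values were seen. The miR-192 pair sets a 5p form without a genome position (mean of 46.2 CPM over all libraries) against miR-192-3p (27.0 CPM). The more abundant miR-192a-2-3p (979 CPM) is a separate feature.

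A few miRNAs held most of the counts over features, in which a sequence listed in several rows counts with the values of 1 row. Shares of the counts over all rows were not computed. The 10 most abundant features took 62.5 ± 8.24% of counts in controls and 67.1 ± 1.82% after transport (n = 3 each, exact two-sided permutation p = 0.4, where 0.1 is the smallest possible). Features with no known miRNA name took 18.7 ± 12.4% and 23.6 ± 2.87% (exact permutation p = 0.5), and the spread in controls came from control 1, at 33.0% (95% Wilson interval 32.9 to 33.0%) against 11.8% and 11.2% in controls 2 and 3. Features without a genome position, a class looked at after the data were seen, took 1.33 ± 0.04% in controls and 0.618 ± 0.10% after transport, with no overlap between the groups (exact permutation p = 0.1, the smallest possible). In control 1 this class included 19990 counts of miR-21-5p_R+1, against 108 and 3237 in controls 2 and 3, and miRNAs of a placental mammal cluster (described below). The share of control 1 without them was not computed, so the lack of overlap may rest on these features in that library. Without control 1 the differences in the shares of the 10 most abundant and of the unnamed features were 9.39 and 12.1 percentage points, each with an exact permutation p of 0.1, the smallest that 2 against 3 can give.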

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

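The alternatives that use features with a genome position alone, library weights, summed rows, removal of 1 or both miR-143-3p forms, or a change combined with the removal of control 1 were chosen after the data were seen. Under the other scalings and filters, limma-voom, limma on the authors' normalized values, known names alone, every row kept and summed rows, edgeR and limma called 0 miRNAs, as with all features and TMM scaling. DESeq2's test called 21. Leaving out 1 library gave 0 to 4 calls, the 4 without control 1. With control 1 left out, DESeq2's test called 73 and edgeR on features with a genome position called 15; library weights in limma-voom called 2. The biological coefficient of variation was 0.644 with all libraries and 0.472 without control 1; the cause was not tested further. Library totals as the only scaling moved the median of all features by -0.22 on the log2 scale and split the features at an unadjusted p under 0.05 into 6 higher and 23 lower, against 22 and 22. Seed families ranged from 0 to 3 and arm pairs from 0 to 9 over the left-out libraries, the highest without control 1 in both. Lists past camera numbered 1, against 4 with no filter (smooth muscle, neural, endothelial and miR-29), 2 with features that have a genome position, 0 with an estimated correlation and 0 to 4 over the left-out libraries, the highest without transport 2; the miR-29 family was among them in 6 of 11 alternatives, with adjusted p from 0.0158 to 0.512 and a positive direction in each; with an estimated correlation 0 lists passed in any of 10 settings tried. The cause of these changes was not tested, and calls lost with an estimated correlation need not reflect members that vary together. The share in the 10 most abundant features stayed higher after transport in each alternative (left-out libraries 3.31 to 9.39 percentage points, and 2.51 without both miR-143-3p forms). That of unnamed features was 1.21 to 12.1 higher over the left-out libraries and turned to -0.323 without PC-3p-1_6188007, which held most of it.

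The sample number as a replicate block gave 0 miRNAs, 0 seed families, 0 arm pairs and 3 lists (neural, endothelial and miR-29; adjusted p = 0.717 for each with an estimated correlation). The labels do not say that the numbers pair samples, and the correlations of deviations between same-numbered samples were -0.29, 0.42 and -0.21; 2 of 6 libraries correlated best with their own number. For the 41 named features, 969 of 1005 fold changes kept their side of the threshold and 36 newly passed it; 34 changed sign, in 10 features, none past the threshold in all 6 libraries by edgeR. At these depths and this spread, a change of 1 on the log2 scale was recovered for 8.42% of simulated features. In that run 200 features were changed at once, so recovery would be lower where few features change. A change of 2 was recovered in 65.0% of arm pairs simulated with the spread of their ratios. There 40 of 70 pairs were moved, so recovery would be lower where few pairs change.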

Other observations

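The tests of the placental cluster and of the naming of miR-143-3p were chosen only after the results they measure were seen. Without control 1, several abundant miRNAs lay close to the threshold by edgeR. miR-101a averaged 5303 ± 669 CPM after transport (n = 3) and 2755 ± 108 CPM in controls 2 and 3, with an adjusted p of 0.0841, and miR-26-5p 18007 ± 1903 against 10057 ± 193 CPM (adjusted p = 0.0841). Both were past the threshold (adjusted p = 0.0428 for each) when features without a genome position were also removed, a setting chosen after the data were seen. The fish miRNAs miR-462 and miR-731, which form a cluster, averaged 17274 ± 4548 against 36092 ± 2925 CPM and 4647 ± 582 against 8311 ± 1082 CPM (adjusted p = 0.0918 for both), and miR-462 had an adjusted p of 0.0521 in that setting. These miRNAs were picked after their values were seen. Features of at most 20 nt whose sequence ends in CCA, 24 in all with miR-2478_L-2 among them, made up 1457 and 1898 CPM (without TMM scaling) in controls 2 and 3, 371 in control 1 and 457 to 611 in the transport libraries. What RNA these short sequences come from was not tested.

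Control 1 stood apart from the other controls. Controls 2 and 3 correlated at 0.961 across features and control 1 with them at 0.859 on average, a gap of 0.102 ± 0.011 (SE over 1000 bootstraps of the features). Lower depth alone is argued against, since the gap was 0.089 ± 0.010 after every library was thinned to the total of control 1. Removing the features without a genome position left a gap of 0.070 ± 0.008, above the bound of 0.05 set beforehand, which argues against miRNAs of another organism without a genome position as the whole of it. A transport library labelled as control 1 stays open: across features, its differences from controls 2 and 3 correlated at 0.246 ± 0.045 with those of the transport mean, below the 0.407 to 0.472 of the transport libraries but not below 0.5 times the lowest of these, the bound set beforehand, and no biological explanation was tested.

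Control 1 also held miRNAs of a gene cluster found in placental mammals. Of 53 such features in the table, 52 were detected in control 1, 26 in control 3 and 22 in transport 3, at 1523, 82.4 and 54.6 CPM (without TMM scaling), and 0 in control 2, transport 1 and transport 2, which allows up to 0.540, 0.451 and 0.453 CPM. Its member miR-127 had 2715, 210 and 213 counts in the libraries that held it, and miR-21-5p_R+1, a form without a genome position, had 19990, 3237 and 2336 counts there against 108 to 193 in the others. Fish reads given mammalian names would be spread about as all counts are, and 86.7% of the cluster's counts lay in control 1, which held 10.3% of all counts. This goes against that explanation, but the comparison was set after the concentration was seen and is no independent test of it. RNA of a mammal in these libraries is a candidate explanation: 34 of the cluster's families were seen together in control 1 and 96.4% of the counts were in features with no genome position.

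The share of features with no known name differed 2.95 times between the lowest and the highest library. Most of it was 1 feature, PC-3p-1_6188007, which held 88.3% to 98.5% of the unnamed counts and begins with the whole sequence of miR-143_1ss20TA. Without it the highest share was 1.94 times the lowest and the order turned, with control 1 lowest at 0.749% and control 3 highest at 1.45%. Since this feature was known to hold most of the unnamed counts, that ratio is no separate test of its naming. The shares do show that most of the difference lay in this 1 feature. Unnamed features took 11.2% to 33.0% of counts with it, and 0.749% to 1.45% of the remaining counts without it. Whether the feature should carry the name of miR-143-3p stays open. Both forms of miR-143-3p together, whatever their names, ran from 15.5% of the counts over features in control 3 to 46.1% in control 1. The ratio of PC-3p-1_6188007 to miR-143_1ss20TA counts was 2.39 in control 1, 1.71 and 1.74 in controls 2 and 3, and 2.01 to 2.30 in the transport libraries (exact permutation p = 0.5 for 3 against 3).

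With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. For miRNAs the real split called 0 and the highest other 0, so 10 of 10 splits gave as many. For seed families the values were 0 and 0, again 10 of 10. For lists the real split gave 1 and the highest other 4, with 5 of 10 splits at 1 or more, and for arm pairs 0 and 2, with 10 of 10. The split that set control 1, transport 1 and transport 3 against the rest had 86 miRNAs at an unadjusted p under 0.05, against 44 for the real one, which was second highest, and 4 to 41 for the other 8. The split with 86 was singled out after the counts were seen, and it called 0 miRNAs, 0 seed families, 0 lists and 0 arm pairs. Whether the libraries hold a structure besides the groups was not tested.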
